A study of Mus musculus with 2 samples.

How the data were processed

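The samples were 2 pools of lung tissue of healthy mice of both sexes at postnatal day 0, strain B6NTac;B6NCrl/Lap. Replicate 1 was made from 15 mice, and the number for replicate 2 is not given in the sources used here. Per the labels, the assay was ATAC-seq with Nextera tagmentation and the assembly mm10. Both samples form 1 group, and the replicate numbers are those of the labels.

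The deposited data were 12 peak lists with 1 line per summit: an IDR-ranked, an IDR-thresholded and a pseudoreplicated list for each replicate and 6 lists made from both. IDR is the irreproducible discovery rate. Peaks were called per replicate, from each replicate's own reads, per the deposited file list. Aligner and peak caller are not given in the sources used here. The score of the deposited IDR lists is a scaled IDR, on which 540 stands for an IDR of 0.05 and 830 for 0.01, and in the other lists it rises with the peak caller's p up to a limit, as read from the values in the files. The fold enrichment in the deposited lists is the authors' value for a summit, taken here to be its ratio over the local background. The −log10 p of each summit is likewise the authors' value from the peak caller in the deposited lists. Sequencing depth is unknown, because the lists give no read counts, so the precision of a single peak could not be worked out.

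A region was an interval of a list, represented by its summit of highest fold enrichment, on 21 chromosomes. Each replicate's IDR-thresholded list was used, and the lists made from both served for 1 alternative. A region was shared when it overlapped a region of the other replicate by at least 1 base, and its partner was the region of largest overlap. The same counts were obtained with bedtools 2.31.1. Overlap and location were set beside 100 circular shifts along the chromosomes. Locations came from GENCODE M21 on the GRCm38.p6 genome, whose chromosomes have the names and lengths of mm10. A promoter summit lay within 1 kb of the start of any annotated transcript, non-coding ones included, and promoter peaks of genes were counted at the starts of protein-coding genes.

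The 24 gene lists held 304 genes, of which 303 were found in the annotation by symbol (Amy2b was not). A gene counted when both replicates had a shared region with a summit within 1 kb of 1 of its starts. The strongest such summit was taken in each replicate separately, and for Ywhaz, Ckm, Nkx2-1, Elf5, Ptch1 and Wnt7b it lay in different regions. Each list was set beside 10000 random lists of protein-coding genes matched on 10 classes of observed over expected CpG within 500 bases of the gene's start. Motifs were 25 consensus sequences, searched within 100 bases of summits over 1 kb from any start and in windows 1 kb to either side. An enriched motif had a ratio of at least 1.5 in both replicates and less than 1.2 for its reversed, uncomplemented sequence. Counting intervals are 95% intervals. No p-values were computed, since there is 1 group and peaks and genes are not replicates.

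Named genes were chosen by a rule fixed before the data were examined, as were the 24 lists, the motifs and the alternatives given below. It takes up to 4 genes per list with the highest mean percentile of fold and up to 4 without a promoter peak, in list order. It also takes the 10 genes with the most regions in the body and 10 kb around it, the 10 regions of highest mean percentile, the 5 strongest regions of each replicate without a counterpart, and 12 genes that are always described. Genes with a peak in a single replicate, genes with a peak in the longer lists and the pairs that differed most were named in addition, after their values were seen. Lists of glucocorticoid targets and immediate early genes were also added then.

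The steps were run on simulated data, as a check of the code. For the overlap, 69.9% of 42700 regions were planted as shared, 100% of these were recovered and 0.724% of the moved ones were called. The planted regions were displaced by less than the width of most regions, so their recovery followed from the design. A planted correlation of 0.9 gave 0.901 over 42700 regions, with the pairing of the values given and not tested. A motif planted in 20% of 5000 windows was found in 20.2%, and in 2.03% of flanks for 2% planted, and 16 motifs that were not planted had ratios of 0.788 to 1.26. Of 21911 genes, 200 were given a promoter peak and all 200 were found, along with 26 neighbours, all of which start within 2 kb of another gene. The planted summits lay inside the 1 kb window, so finding all 200 also followed from the design. Of 300 lists with no planted excess, 6% lay outside the central 95% of random lists.

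The alternatives were the pseudoreplicated lists, an IDR of at most 0.01, a reciprocal overlap of 50%, summits within 100 bases, promoter windows of 0.5 kb and 2.5 kb, each replicate left out, the outermost start alone, the conservative list of both replicates, motif windows of 50 bases, flanks 5 kb away and −log10 p in place of fold. The remaining lists of both replicates and the IDR columns were not analysed here. Alignments to the mitochondrial genome used blastn 2.17.0. Its blastn task served for the regions of highest −log10 p, the random regions and the removed regions. Its less sensitive megablast task served for the full set of shared regions, and the aligned shares printed for shared regions come from it. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.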

Results

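Open chromatin was measured by ATAC-seq in mouse lung on the day of birth (postnatal day 0). In this assay the Tn5 transposase cuts accessible DNA and adds sequencing adapters, so that regions rich in cuts mark open chromatin. The series held 1 group with 2 replicates. Replicate 1 was lung tissue pooled from 15 mice, and replicate 2 was a second pool of healthy mice of both sexes. No treatment, other tissue or other age was part of the series. The comparisons were therefore between the replicates, between genomic locations, between gene lists and between sequence motifs. Peaks had been called in each replicate on its own. The lists give no read counts, so the depth of the libraries is unknown, and the fold enrichment of a peak is the authors' value for that peak.

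The open regions of the newborn lung were largely the same in both pools, and the strongest ones were found in both nearly without exception. Among the strongest were the promoters of Cdc25c, a cell cycle phosphatase gene, at 34.0 ± 0.139-fold enrichment (SD, n = 2), and of Cep128, a centrosome gene, at 30.6 ± 1.29-fold. Replicate 1 had 42700 open regions and replicate 2 had 40273, a mean of 41486.5 ± 1716 (SD, n = 2). A region was an interval of the deposited list, and 52.9% ± 1.23 of the regions held more than 1 summit. The regions covered 28.6 ± 0.847 Mb, or 1.05% ± 0.0311 of the chromosomes.

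In replicate 1, 34404 regions (80.6%) overlapped a region of replicate 2 by at least 1 base. In replicate 2, 34367 regions (85.3%) overlapped a region of replicate 1. After replicate 2 had been shifted along its chromosomes 100 times, at most 2.51% of the regions of replicate 1 and 2.67% of those of replicate 2 overlapped. Of the tenth of regions with the highest fold enrichment, 99.98% were shared in replicate 1 and 100% in replicate 2, against 54.7% and 65.3% of the tenth with the lowest. Of the regions that were not shared, 94.1% in replicate 1 and 95.6% in replicate 2 overlapped the longer, ranked list of the other replicate. That left 492 regions of replicate 1 and 261 of replicate 2 with no counterpart. The strongest of these lay in an intron (chromosome 1, 83900097 to 83900495, 10.4-fold), 152966 bases from the nearest protein-coding start (that of Pid1), and between genes 25314 bases from Lrrc8d (chromosome 5, 105849664 to 105849982, 10.2-fold) in replicate 1. In replicate 2 they lay 39832 bases from Ttpa, the gene of a vitamin E transfer protein (chromosome 4, 19967775 to 19968252, 11.2-fold), and in an intron 6653 bases from Gdi2 (chromosome 13, 3544883 to 3545346, 9.32-fold). The remaining regions of the 5 strongest lay 209028, 575545 and 120705 bases from the nearest protein-coding starts (Arl15, Nrg3 and Bambi) in replicate 1. In replicate 2 they lay 36924 bases from 3110009E18Rik, 47122 bases from Barhl1 and at the promoter of Dlgap5. Their fold enrichment was 8.34 to 9.87.

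Across the 34404 shared regions of replicate 1, log2 fold enrichment had a Spearman rho of 0.914 and a Pearson r of 0.918 with that of the partner in replicate 2. Regions are not independent replicates, and no p-value is given. After centring on the median, 95.1% of the regions lay within 0.5 on the log2 scale, and 167 differed by more than 1. With reciprocal best partners only, 37 of 33997 pairs differed by more than 1. In 20 of them the value was higher in replicate 2, among them pairs in an intron 5236 bases from the start of Twsg1, a BMP modulator gene (3.95-fold and 13.5-fold), and at the promoter of Srsf6, a splicing factor gene (6.08-fold and 17.2-fold). In 17 it was higher in replicate 1, among them the promoters of the autophagy gene Map1lc3b (9.91-fold and 3.62-fold) and of Slco2a1, a prostaglandin transporter gene (12.5-fold and 5.62-fold). These single pairs were chosen after their values were seen, and with 1 value per pool no difference of a single region was tested.

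**Figure D1:**
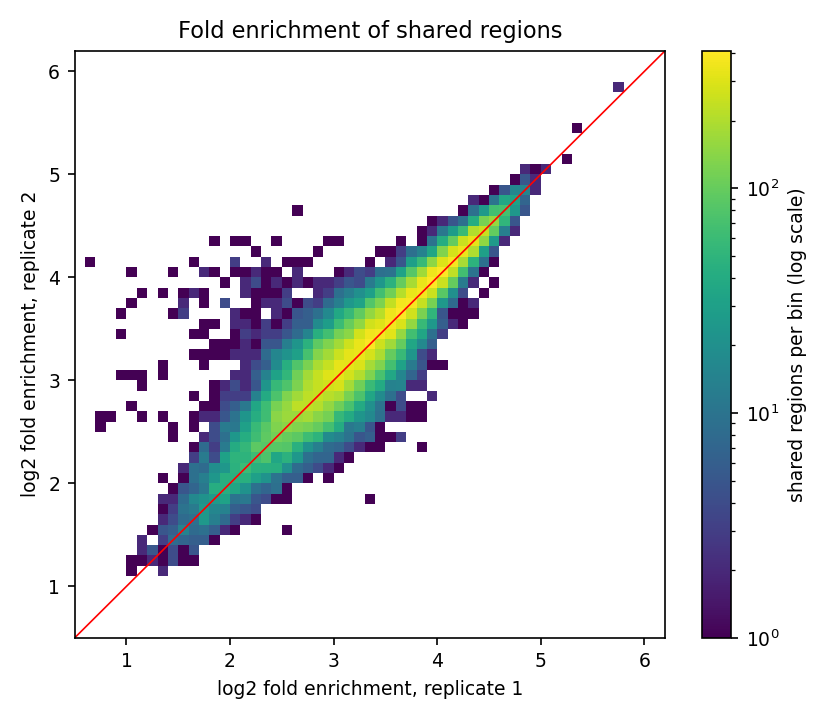
Log2 fold enrichment of the regions of replicate 1 (horizontal axis) and of their partners in replicate 2 (vertical axis), with the number of regions per bin of 0.1 by 0.1 in colour on a log scale and the line of equal values in red. The regions lie along the line (Spearman rho 0.914), and 167 of them differ by more than 1 after centring, against 37 pairs when only reciprocal best partners are counted.

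Promoters made up a large part of the open regions and had a higher median fold enrichment than introns and intergenic DNA. Over all regions of each replicate, 38.7% ± 1.17 (SD, n = 2) of the regions had their strongest summit within 1 kb of an annotated transcription start site, 6.22 times the 6.23% of shifted regions. Introns held 33.0% ± 0.723 of the summits, against 39.3% of shifted ones, and intergenic DNA held 24.8% ± 0.414 against 51.1%. Exons away from promoters held 3.43% ± 0.0354, close to the 3.33% of shifted regions. The median fold enrichment was 12.4 ± 0.33 at promoters, 7.97 ± 0.342 in introns and 8.36 ± 0.405 between genes, so promoter regions exceeded the others by more than the spread between replicates. Promoters made up 43.6% of the shared regions and 15.4% of those that were not shared between the thresholded lists. The 14 constitutively expressed genes of the reference list all had a promoter peak in both replicates. Among them, Rplp0, which codes for a ribosomal protein, had 21.2 ± 0.0185-fold enrichment, Sdha of the respiratory chain 20.9 ± 1.31, B2m 19.2 ± 0.451 and the glycolysis gene Pgk1 18.9 ± 0.143. Others were far lower, with Ubc at 3.87 ± 0.0291-fold (mean percentile 2.64 of all regions), Actb at 7.56 ± 0.0727 (34.4) and Eef2 at 9.07 ± 0.658 (49.4). For Ywhaz different regions were strongest in replicate 1 (8.78-fold) and replicate 2 (9.64-fold). Another protein-coding gene starts within 2 kb of Sdha, Ubc and Eef2.

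**Figure D2:**
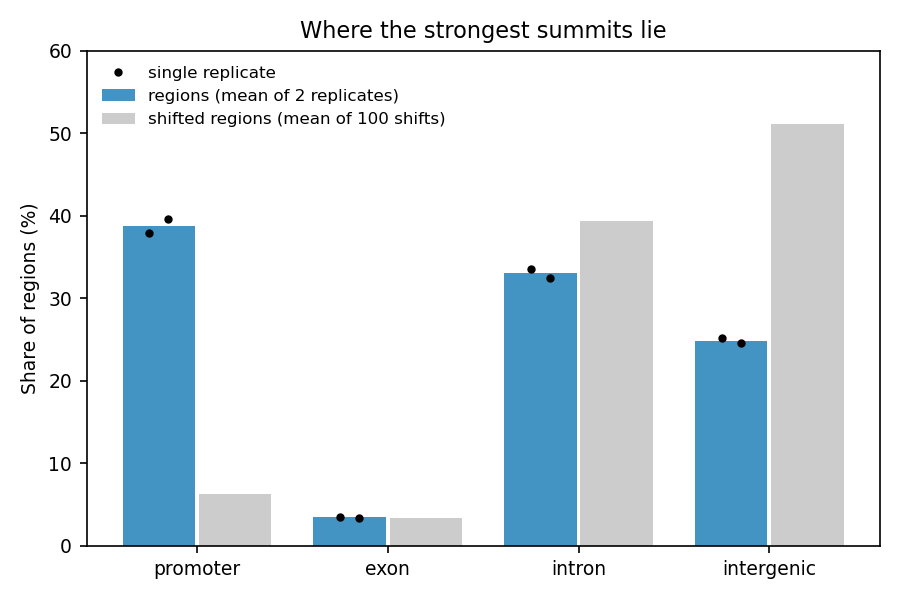
Share of regions (percent, vertical axis) whose strongest summit lay at a promoter (within 1 kb of a transcription start site), in an exon, in an intron or between genes. Blue bars are means of the 2 replicates, black points single replicates and grey bars the mean after 100 shifts along the chromosomes. Promoters held 38.7% of the regions against 6.23% of shifted ones.

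Of 21911 protein-coding genes, 12711 (58.0%) had a promoter peak shared by both replicates. This share rose with the CpG content of the promoter, from 5.66% in the lowest of 10 CpG classes to 95.7% in the highest. Gene lists were therefore set beside 10000 random lists of the same size with the same CpG classes. These percentiles describe the 2 libraries and are not p-values, since genes are not replicates.

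Alveolar genes had open promoters nearly throughout, while few leukocyte genes and few genes of tissues other than lung had a promoter peak in both replicates. All 12 genes of the list of alveolar type 2 cells, which make surfactant, had a promoter peak in both replicates, and no random list had as many (random mean 44.0%). The highest were Etv5, a transcription factor gene (16.0 ± 1.06-fold), Lpcat1, of surfactant lipid synthesis (15.3 ± 1.85), Abca3, of lipid transport into lamellar bodies (13.1 ± 1.34), and Napsa, an aspartic protease gene (11.4 ± 0.54). Of the list of alveolar type 1 cells, the thin cells of gas exchange, 11 of 12 had a peak (random mean 68.3%, 430 of 10000 lists as high). The highest were Rtkn2 (13.6 ± 0.647), Emp2 (13 ± 1.07), the tight junction gene Cldn18 (12 ± 0.599) and Lmo7 (12 ± 0.697), and Pdpn had none in either replicate. Of 14 lung epithelial transcription factor genes, 13 had a peak, with Klf5 at 17.7 ± 0.55-fold, Gata6 at 12 ± 0.256, Foxa2 at 11.7 ± 0.158 and Cebpa at 10.9 ± 0.317, and Hnf1b had none except in the longer pseudoreplicated lists. Of 16 lung signalling genes, 14 had a peak (random mean 61.8%, 44 of 10000 lists as high), but 7 when only the outermost start of each gene was counted. Bmp4 had 14.0 ± 1.32-fold, the fibroblast growth factor receptor gene Fgfr2 13.5 ± 0.885, the retinoic acid receptor gene Rarb 12.8 ± 0.0316 and Notch2 12.3 ± 1.17, while Shh and Vegfd had none (Vegfd had a peak in the longer lists of both). Another protein-coding gene starts within 2 kb of Abca3, Sftpc, Lmo7, Col4a3 and Fgfr2, so their peaks cannot be assigned to a single gene.

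The vascular and mesenchymal lists lay within the range of random lists. Of 15 endothelial genes, 10 had a shared promoter peak (66.7%, random mean 54.7%). Tie1, an endothelial receptor, had 17.9 ± 1.19-fold, Vwf 12 ± 0.844, the lymphatic regulator Prox1 10.8 ± 0.783 and Erg 9.22 ± 0.239. Emcn and Car4 had none. Of 15 mesenchymal genes, 11 had a peak (73.3%, random mean 57.5%), with the matrix genes Fn1 (13.9 ± 0.199) and Col1a2 (11.4 ± 1.24), the lipid droplet gene Plin2 (10.3 ± 1.03) and Tcf21 (9.53 ± 0.314). Tbx5, Fgf10 and Wnt5a, which take part in lung bud outgrowth and patterning, had none, although each had a promoter peak in the longer pseudoreplicated lists of both replicates. Of 12 smooth muscle and pericyte genes, 5 had a shared peak, among them the contractile genes Myh11 (12.1 ± 0.348), Acta2 (8.58 ± 0.465), Des (8.12 ± 0.286) and Tagln (7.32 ± 0.373). Cnn1, Notch3 and Lgr6 had none. With the longer lists 11 of the 12 had a peak, Cnn1 and Lgr6 among them, and with the conservative list of both replicates 10. Replicate 1 alone had 66.7% of this list and replicate 2 alone 50%, against 41.7% shared, so that the share depended on the replicate. Of 8 mesothelial genes, 4 had a peak (Krt19 13.2 ± 0.266, Krt8 8.35 ± 0.892, Aldh1a2 8.06 ± 0.545, Msln 7.31 ± 1.03), and Wt1, Upk3b, Upk1b and Lrrn4 had none, although Upk3b and Upk1b had a peak in the longer lists. Another protein-coding gene starts within 2 kb of Pecam1 and Cspg4, which also had a shared peak.

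Of 12 ciliated cell genes, 7 had a peak (58.3%, random mean 77.7%). The regulators of ciliogenesis Rfx3 (19.9 ± 0.638), Rfx2 (17.5 ± 0.351) and Foxj1 (15.6 ± 0.00917) and the dynein gene Dnah9 (14.7 ± 1.11) were the highest, and Dnah5, Hydin, Spag6l and Myb had none, although Hydin and Spag6l had a peak in the longer lists. Of 8 neuroendocrine genes, Scg5 (13.3 ± 2.65), Syp (9.23 ± 2.01) and Uchl1 (9.04 ± 1.75) had a peak, and 253 of 10000 random lists had as few. Ascl1, Calca, Chga and Insm1 had none. In the longer lists 6 of the 8 had a peak in both replicates, Ascl1, Chga and Insm1 among them. Of 12 secretory and basal airway genes, Aldh1a1 alone had a shared peak (13.5 ± 1.82). This lay within the range of random lists (random mean 21.7%, 2176 of 10000 as low), since the promoters of these genes are poor in CpG. Scgb1a1, Scgb3a1, Scgb3a2 and Cyp2f2, which mark club cells, had none, and Muc5b had a peak in replicate 2 alone, so that the count was 2 without replicate 1. In the longer lists Scgb1a1 and Scgb3a2 had a promoter peak in both replicates. The 14 leukocyte genes had no shared promoter peak (random mean 20.3%, 402 of 10000 random lists had none). Ptprc, Csf1r, Lyz2 and Cd68 had none in either replicate, and Spi1 and S100a8 had a peak in replicate 1 alone. Of 12 erythroid genes, Epor alone had a shared peak (6.06 ± 1.39), where the random mean was 29.8% and 444 of 10000 random lists had as few. The share of the erythroid list was 8.33% in replicate 1 and 33.3% in replicate 2, where Hba-a2, Slc4a1 and Tal1 also had a peak. Hbb-bt, Hbb-bs, Hba-a1 and Gata1 had none in either, and the 3 globin genes among them had a peak in the longer lists of both.

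The Hox genes, which specify position along the body axis, had few promoter peaks in the lists of single replicates for their CpG content, and more in the other lists. No gene of the posterior list, 16 genes of groups 9 to 13, had a promoter peak in either replicate, while random lists averaged 83.3% and none of the 10000 had as few. Hoxa9, Hoxa10, Hoxa11 and Hoxa13 were among those without a peak. Of 16 anterior Hox genes, 7 had a peak (43.8%, random mean 70.1%, 79 of 10000 lists as low). These were Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxb1, Hoxb4 and Hoxb5, with Hoxa5 at 13 ± 0.000742-fold, Hoxa1 at 9.31 ± 0.988, Hoxb4 at 7.51 ± 1.01 and Hoxb1 at 6.65 ± 0.00991. Hoxa3, Hoxb3, Hoxb6 and Hoxc4 had none. In the longer lists 13 of the 16 anterior genes, Hoxa3, Hoxb3 and Hoxb6 among them, and 7 of the 16 posterior genes, Hoxa10 and Hoxa13 among them, had a promoter peak in both replicates. The conservative list of both replicates, which has the same IDR threshold, held a promoter peak of 9 anterior and 4 posterior genes.

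Of 95 genes of 8 lists of other tissues, 13 (13.7%) had a shared promoter peak, against a random mean of 35.8%, and none of the 10000 random lists had as few. The hepatocyte list had no shared peak, with Alb, Apoa1, Apoa2 and Ttr without one in either replicate and Apob with one in replicate 2 alone. Of the neuron list, Snap25 (14.2 ± 1.58) and Syt1 (8.59 ± 1.11) had a peak, and Rbfox3, Gad1, Gad2 and Slc17a7 had none. Of the cardiomyocyte list, Myl4 (16.8 ± 0.147), Myh7 (11.9 ± 0.463) and Ryr2 (10.1 ± 0.12) had a peak, and Nkx2-5, Myh6, Tnnt2 and Tnni3 had none. In the longer lists 6 genes of this list had a peak, Tnnt2 and Tnni3 among them. Of the skeletal muscle list, Actn3 (21.3 ± 0.156) and Ckm had a peak (for Ckm, different regions were strongest in replicate 1, with 9.43-fold, and replicate 2, with 10.0-fold), and Myod1, Myog, Myf5 and Acta1 had none. In the photoreceptor list these were Opn1sw (16.2 ± 0.49), Rom1 (12.7 ± 1.12) and Gnat1 (7.5 ± 0.152), in the germ cell list Dazl (16.7 ± 0.185), in the pancreas list Cela1 (9.78 ± 2.41) and in the intestinal list Muc2 (6.58 ± 1.17). Rho, Crx, Ddx4, Sycp3, Ins1, Ins2, Cdx1 and Cdx2 had none, except for Sycp3 in the longer lists. Another protein-coding gene starts within 2 kb of Actn3, Ckm, Myl4 and Rom1, so their peaks cannot be assigned to a single gene.

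Over the 12 lung lists together, 91 of 150 genes (60.7%) had a shared promoter peak, 47.0 percentage points more than in the other-tissue lists. The SD of this difference between the single replicates was 2.08 points. It ranged from 38.1 points, when only the outermost start of each gene was counted, to 57.2 points with the longer peak lists. The random mean was 53.7% for the lung lists, and 220 of 10000 random lists were as high. For the other-tissue lists the random mean was 35.8%, so part of the difference between the 2 kinds of list goes with promoter CpG. Random lists were not matched on the number of starts per gene. With the outermost start alone the shares were 48.7% for lung and 10.5% for other-tissue lists. No random mean is given for that setting, so the lung excess over random lists is not shown to hold there.

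**Figure D3:**
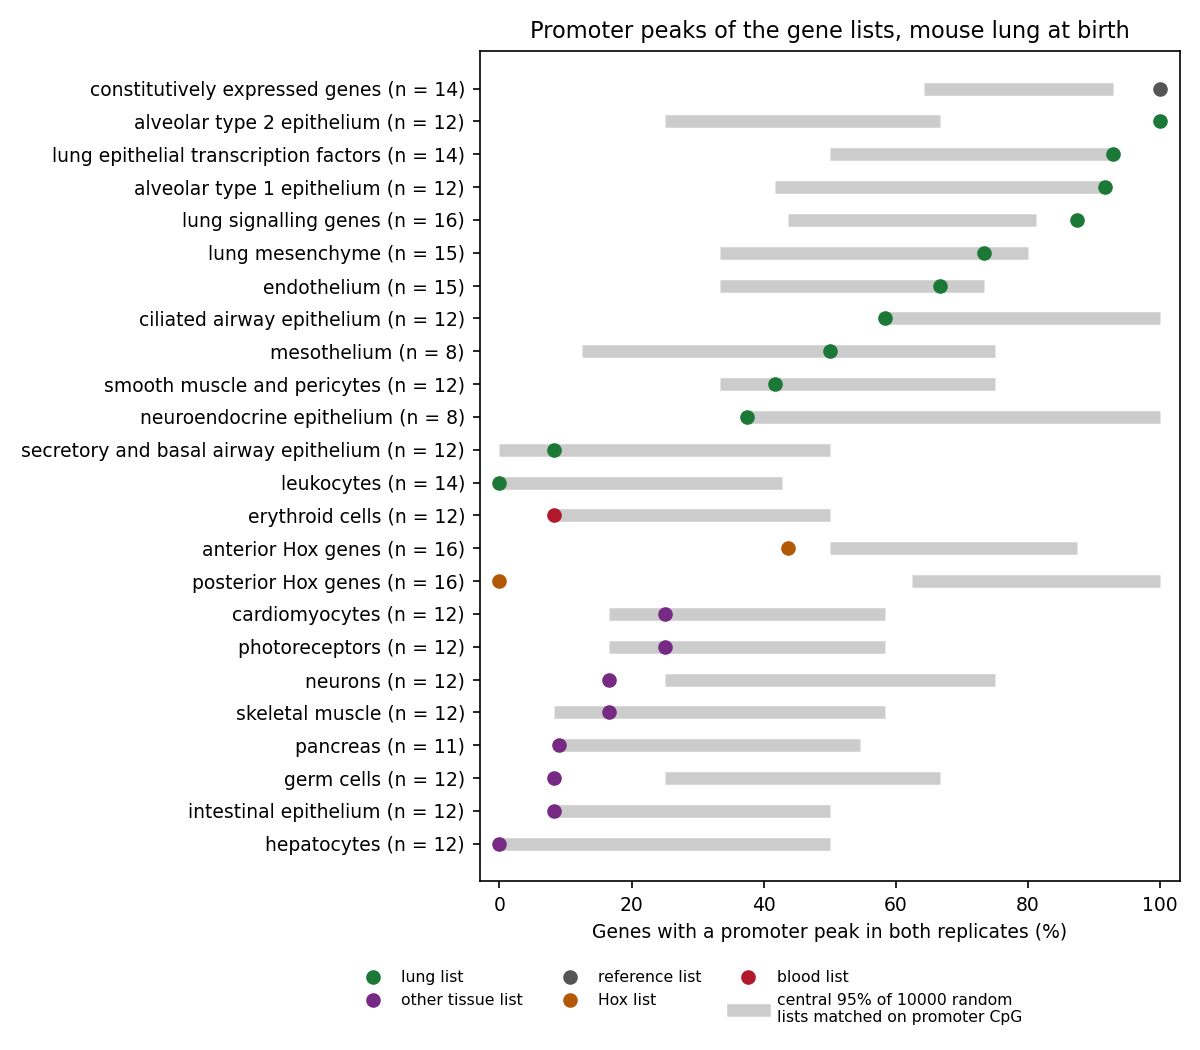
Percent of the genes of each list with a promoter peak in both replicates (points, coloured by the kind of list, with the number of genes in brackets) and the central 95% of 10000 random lists matched on promoter CpG (grey bars). The list of alveolar type 2 genes lies at 100%, above its random range, and the posterior Hox list at 0%, below its range.

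At single loci, the surfactant and alveolar genes differed widely in the fold enrichment of their promoter regions. If this value is a ratio over the local background, as taken here, a low value need not mean a less open promoter. Sftpb, the gene of surfactant protein B, had a promoter region of 10.9 ± 0.346-fold at chromosome 6, 72303607 to 72304782, and a region of 6.25 ± 0.844-fold downstream between genes. Sftpc, the gene of surfactant protein C and a marker of alveolar type 2 cells, had 4 shared regions on chromosome 14. The region at its start (70523985 to 70524639) reached 3.71 ± 0.202-fold, at percentile 2.00 of the regions in replicate 1 and 2.36 in replicate 2. The strongest of the 4, at 6.2 ± 0.41-fold, lay 3057 bases upstream (70526622 to 70527287), and the other regions (70520022 to 70520843 and 70529965 to 70530820) had 4.02 ± 0.759-fold and 4.56 ± 0.87-fold. Ager, an alveolar type 1 marker on chromosome 17, had 5 regions, all within 1 kb of some transcription start site in a gene-dense stretch. The region at its own promoter (34597521 to 34598423) had 8.65 ± 0.812-fold, and the strongest (34603336 to 34604473), 5921 bases from its nearest start, had 11.3 ± 0.193-fold. The other 3 had 3.21-fold to 4.41-fold. Hopx had promoter regions of 9.53 ± 0.297-fold (chromosome 5, 77094663 to 77095448) and 7.37 ± 0.0415-fold (77114792 to 77115590) and an intron region of 7.83 ± 0.175-fold.

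Nkx2-1, the transcription factor gene that marks lung epithelium, had 4 regions on chromosome 12 of 5.39 ± 0.425-fold to 6.08 ± 0.377-fold, the highest at 56535462 to 56536316. Foxa2 had a region of 11.7 ± 0.158-fold with 4 summits at its promoter (chromosome 2, 148045669 to 148046756) and a second of 5.45 ± 0.436-fold downstream. Foxf1, a regulator of lung mesenchyme, had a promoter region of 8.65 ± 0.486-fold (chromosome 8, 121083006 to 121084667) and an exon region downstream that differed between replicates (4.82-fold and 7.85-fold). Tbx4 had regions at both of its promoters, of 7.82 ± 0.441-fold (chromosome 11, 85885749 to 85886526) and 5.80 ± 1.83-fold (85896272 to 85896906). Its paralogue Tbx5 (chromosome 5, 119832668 to 119885219) had no shared region in its body or within 10 kb of it. Pecam1, an endothelial adhesion gene on chromosome 11, had 6 regions, and the strongest was not the region at its start (7.28 ± 0.204-fold) but an intron region of 13.7 ± 1.44-fold at 106722740 to 106723379. The other 4 intron regions had 4.06-fold to 8.46-fold. Hoxa5 had its promoter region (chromosome 6, 52203753 to 52204852) and regions of 6.51 ± 0.00431-fold and 8.53 ± 2.05-fold to its 3' side. The 6.51-fold region (52191780 to 52192244) was the promoter region of the neighbouring gene Hoxa4. Foxj1 had 1 region, at its promoter (chromosome 11, 116335124 to 116336006).

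The regions with the highest fold enrichment lay mostly away from the starts of protein-coding genes. The highest lay on chromosome X (143482936 to 143483180), 35531 bases from the start of Pak3, at 55.8 ± 2.04-fold, and on chromosome 2 (69355469 to 69355735), 12986 bases from Abcb11, at 55.8 ± 0.516-fold. Next were regions on chromosome 5 (60042692 to 60043146, 42.0 ± 1.69-fold), far from any protein-coding gene, and on chromosome 2 (3964426 to 3964690, 37.9 ± 1.61-fold), 53156 bases from Frmd4a. Besides the promoters of Cdc25c (chromosome 18, 34751443 to 34752007) and Cep128 (chromosome 12, 91383932 to 91384929), the 10 highest held regions of 30.0-fold to 32.8-fold whose nearest protein-coding genes were Gm13283, Tyrp1 (831184 bases away), Gm5426 and Myl12b. Of these 10, the regions on chromosomes 5, 4 (80002696 to 80003058) and 10 (96077546 to 96077951) aligned to the mitochondrial genome over 84.0%, 99.4% and 86.7% of their length, and the region near Abcb11 over 48.3%.

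The genes with the most shared regions were long. Nav2, of neurite growth (31.5 regions over 701 kb, mean of the replicates), Tns1, which codes for the focal adhesion protein tensin 1 (30.0 over 214 kb), Syn3 (22.0), 2010111I01Rik (21.0), Maml3, a Notch coactivator (21.0), Ablim1 (20.5) and the calcium channel gene Cacna1c (20.5) were among the 10 highest. Tns1 had 12.8 regions per 100 kb, against 2.58 over all protein-coding genes, and the median gene had 1. Gm20388 (195 regions over 4435 kb), Fgfr2 (69 over 2961 kb) and Gm37240 (21.0 over 1391 kb) were counted over annotated models that span many other genes, so their numbers are not of a single gene.

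At open regions away from promoters, the motifs of CTCF, NKX2, FOX, TEAD and some other factor families were more frequent at the summit than 1 kb away. CTCF, which organises chromatin loops, had the highest ratio among the motifs with flank sites, at 16.3 ± 0.598 (SD, n = 2), with a motif at 3.23% of the summits. NKX2, the family of Nkx2-1, had a ratio of 2.07 ± 0.0564 (5.06% of summits), FOX, the family of Foxa and Foxf1, 1.63 ± 0.0314 (7.03%), and TEAD, which acts with Yap1, 3.09 ± 0.171 (10.7%). ETS, the family of Erg, had 3.26 ± 0.218, and SRF, a regulator of contractile genes, 2.84 ± 0.0299. These 6 families and NFI met the rule of a ratio of at least 1.5 in both replicates with less than 1.2 for the mirrored motif. They were 7 of the 25 motifs tested, at 26516 distal regions in replicate 1 and 24341 in replicate 2. Among the 7, NKX2 and FOX had the lowest ratios. For CTCF and NFI the mirrored motif was too rare to serve as a control. Mirrored CTCF had 1 summit and 5 flank sites in replicate 1 and 0 and 2 in replicate 2, and mirrored NFI 0 and 2, and 0 and 1. NFI rested on few sites, 20 at summits and 5 in the flanks in replicate 1 (ratio 8.0, 95% counting interval 3.0 to 21.3) and 15 and 3 in replicate 2 (ratio 10.0, interval 2.89 to 34.5).

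A ratio of at least 1.5 in both replicates was found for 16 motifs, of which 9 did not meet the rule. For RFX (4.38 ± 0.0257) and NRF1 (2.53 ± 0.128) this was because the mirrored motif had no flank site in at least 1 replicate, so that its ratio was undefined, which says nothing about the motif. CEBP (4.45 ± 0.413) missed it by the mirrored ratio of replicate 2 (0.905 and 1.23). The others included the glucocorticoid response element, GRE (6.83 ± 2.12, mirrored 1.84, at 0.754% of summits in replicate 1 and 1.34% in replicate 2), CREB (5.19 ± 1.14, mirrored 1.58) and AP-1 (3.28 ± 0.472, at 11.1% and 13.7% of summits, mirrored 1.3). They also included the E-box CAGCTG (2.34 ± 0.0634, at 23.2% of summits, mirrored 1.5) and STAT (2.13 ± 0.104, mirrored 1.29). For SP/KLF (3.37) the mirrored sequence is the motif itself, so the rule could not be met. MEF2 (0.578 ± 0.0201), the POU octamer (0.782 ± 0.00287) and TCF/LEF (0.797 ± 0.0389) were less frequent at summits than in the flanks. Their mirrored sequences had ratios of 0.291, 0.449 and 0.822. For MEF2 and the POU octamer the mirrored sequence was thus lower still, and for TCF/LEF it was nearly as low. A low ratio was therefore not particular to these motifs. GATA, SOX, RUNX and HNF4 had ratios of 1.15 to 1.3, with mirrored ratios of 0.598, 1.4, 0.563 and 0.635. The DR1 element of nuclear receptors had 0.596, with 8 and 9 sites at summits. REST had 11 sites at summits in each replicate and none in the flanks, a ratio of at least 7.33 when 3 flank sites are taken as the limit over the whole set. CTCF did not meet the rule with windows of 50 bases, where the mirrored motif had no flank site in replicate 2. NFI did not with flanks 5 kb away, where its ratios were 8.0 and 4.29 but its mirrored motif had no flank site in either replicate, so that the rule could not be applied. NFI also did not with the pseudoreplicated lists. ETS did not with flanks 5 kb away, where its mirrored motif had 1.24 and 1.22.

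Some motifs differed in frequency between the replicates. GRE had the largest ratio between the full lists, with 200 distal regions in replicate 1 (95% interval 0.657% to 0.866%) and 325 in replicate 2 (1.2% to 1.49%). Among the 20000 distal regions of highest fold in each list, the rate in replicate 2 over that in replicate 1 was 1.81 for GRE (1.49 to 2.21), 1.38 for CREB (1.11 to 1.72), 1.23 for AP-1 (1.16 to 1.3) and 1.13 for CTCF (1.01 to 1.27). It was below 1 for TEAD (0.925, 0.872 to 0.982) and GATA (0.892, 0.823 to 0.967). The intervals are of counting alone, and with 1 library per pool no difference between pools was tested.

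**Figure D4:**
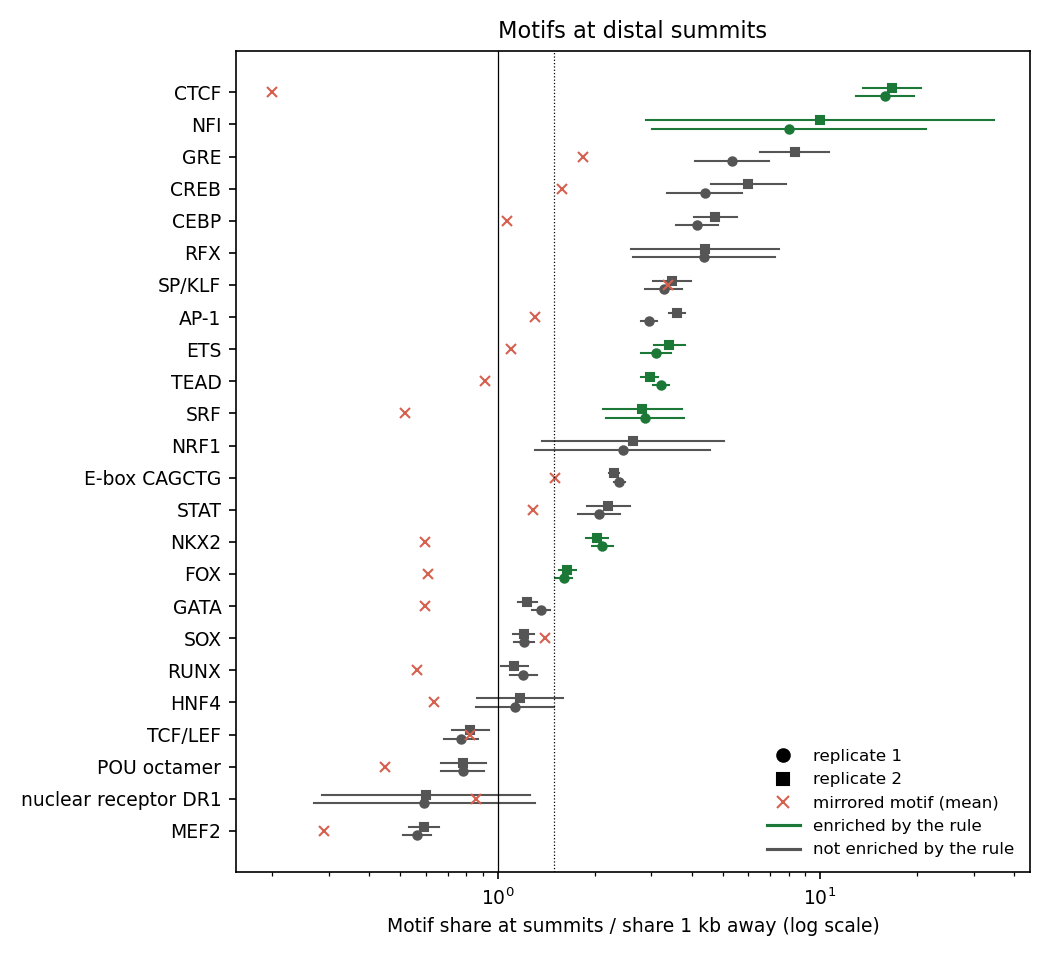
Share of distal regions with a motif within 100 bases of the summit divided by the share in windows 1 kb away (horizontal log axis) for 24 of the 25 motif families, in replicate 1 (circles) and replicate 2 (squares), with 95% counting intervals as lines. Crosses show the mean ratio of the mirrored motif, drawn where it was defined and above 0, and the dotted line the limit of 1.5. REST, with no flank site, is not drawn, and CTCF has the highest ratio (16.3).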

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

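The comparison below was made after the lists had been examined, and both mitochondrial tests were specified after the pattern was seen and before their own results.

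In replicate 1, 224 summits of the ranked list passed the IDR threshold and were absent from the thresholded list, and in replicate 2, 221 were. They drew attention because they lie outside the lists used for the comparisons and exceed the 3 that a count of 0 allows. They were 0.289% and 0.297% of the passing summits. Of these, 70 and 67 lay on scaffolds outside the chromosomes and 154 and 154 on chromosomes. The deposited file list derives the thresholded lists also from a further file, which the ranked lists lack and whose content is not given in the sources used here, so why the summits were left out is not known.

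The region of highest −log10 p among them lay at chromosome 1, 24611586 to 24616165 (6535 in replicate 1, with 3.36-fold enrichment), and aligned to the mitochondrial genome over 100% of its length. It was an exception. The removed regions on chromosomes numbered 139 over both lists, with a place removed in both replicates counted in each. Of these, 2 did so over at least 50%, and they were this same locus, 1 in each replicate. Within the shared regions, the 3 highest in −log10 p lay at chromosome 12, 97061368 to 97061856, and chromosome 2, 22589144 to 22590230 and 22587518 to 22588359, while the fourth had 1564. All 3 of the 3 aligned to mitochondrial DNA over at least 50% of their length (74.6%, 100% and 99.0%), and 0% of 300 random shared regions did, so reads from the mitochondrial genome may have been placed there. A repeated nuclear sequence does not account for all of them, since 1 of the 3 regions had a further nuclear copy (95% identity over at least 50% of the length). All 34404 shared regions were searched with a less sensitive setting (megablast), by which 12 aligned to mitochondrial DNA over at least 50% of their length. This number may therefore be too low. No biological explanation was tested.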

How the results depend on the processing

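The use of summits and the omission of genes with a close neighbour were chosen after seeing the data. No paired analysis was possible because there was only 1 group. With the pseudoreplicated lists, regions per replicate rose to 94731, rho was 0.857, the promoter share 25.0% and the marker difference (lung minus other-tissue lists, not corrected for promoter CpG) 57.2 points. With an IDR of at most 0.01 the last 3 were 0.923, 44.3% and 41.8 points. Counting summits gave 75754 per replicate. Summits within 100 bases gave a shared percent of 78.2, and a reciprocal overlap of 50% a rho of 0.927, and −log10 p a rho of 0.917. Promoter windows of 500 bases and 2.5 kb gave promoter shares of 34.6% and 46.1% and marker differences of 50.2 and 42.7 points. The conservative list gave 34.5% and 52.5 points, the outermost start alone 38.1 points and genes without a close neighbour 49.3 points. Without 1 replicate the marker difference was 47.9 to 50.9 points. The number of enriched motifs was 5 to 9, against 7, and with the pseudoreplicated lists it was 7 with CEBP in place of NFI. With flanks 5 kb away the HNF4 ratio minus 1 was −0.158, below 0, and its cause was not tested. Among the counts per list, 36 settings moved and 180 stayed within 1.5 times. The erythroid count of 1 became 8 with the pseudoreplicated lists, 6 with the conservative list, 4 without replicate 1 and 0 with an IDR of at most 0.01, the smooth muscle count of 5 became 8 without replicate 2, the secretory count of 1 became 4 with the pseudoreplicated lists, 3 with the conservative list and 0 with the outermost start, and the leukocyte count of 0 became 2 with the pseudoreplicated or the conservative list and without replicate 2. Among the motif ratios 56 moved by more than the spread of the replicates and 87 did not. The 87 include all ratios of the settings that left 1 replicate out. These could not move by this measure, because a single replicate always lies within that spread of the mean. REST had no flank site at the main setting and therefore no ratio to compare.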

Other observations

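The patterns of this part were seen in the data first. The bounds of their tests were written before the results, but the restriction to reciprocal partners, the GC-standardised rate and the reading of the glucocorticoid target test were chosen after results had been seen.

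The glucocorticoid response element, GRE, was more frequent at distal summits of replicate 2, as CREB and AP-1 were to a smaller degree. Neither a longer list in replicate 1 (ratio 1.81 among equal numbers of regions, 1.49 to 2.21, and 1.81 after standardising GC) nor GC bias accounts for it, since 189 regions with the motif were higher in replicate 2 by 0.23 on the log2 scale (0.21 to 0.28) than regions matched on GC and fold, and by 0.24 with all partners, in lists whose folds are scaled separately. A different makeup of cells stays open: among lung lists of at least 10 regions the largest median was −0.081 on the log2 scale (leukocytes, −0.17 to −0.02), but the neuroendocrine list, with 5 regions, had 0.37 (−0.06 to 0.42), above the 0.25 of the motif regions, and so met the bound written for this explanation, which named no minimum number of regions. Stronger glucocorticoid signalling in pool 2 also stays open as a hypothesis, but its 23 target genes gave it no support. These genes lay at percentile 20.9 of random lists (40.05 with all partners), with 7 higher in replicate 2. The 20 immediate early genes lay at percentile 1.47. The value of 20.9 met the bound of 50 written against that hypothesis, but the bound was judged too loose after the value was seen, because it lies inside the spread of random lists and averages regions with and without the motif.

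Few leukocyte, erythroid and secretory airway genes had promoter peaks. All 3 lists lay within the central 95% of random lists (random means 20.3%, 29.8% and 21.7%), the first 2 at its lower end. For leukocyte and secretory genes this range began at 0%, so no count could have fallen below it. Of the 10000 random lists, 402, 444 and 2176 had as few. Of the 36 genes without a peak, 12 (33.3%) gained one in the pseudoreplicated lists of both replicates, against 19.2% of all genes and 9.76% of the other-tissue genes. These shares were not matched on promoter CpG. Weak peaks below the threshold may explain part of the low counts. The share of 33.3% lay between the bounds set beforehand. It was 63.6% for erythroid genes (Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2 among them), 27.3% for secretory genes (Scgb1a1, Scgb3a2 and Muc5b) and 14.3% for leukocyte genes (Spi1 and S100a8). No biological explanation was tested.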
